A study of Mus musculus with 233 samples.

How the data were processed

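Bulk RNA sequencing of mouse striatum was analysed from 233 libraries in 30 groups. Per the labels, heterozygous zQ175 knock-in mice, in which exon 1 of the Huntingtin gene Htt was replaced by human HTT exon 1 with an expanded CAG repeat, and wild-type (WT) littermates were injected in the striatum of both hemispheres with adeno-associated virus. The virus called nZFP carried the zinc finger repressor ZFP30645, directed at expanded CAG repeats, under the neuronal human synapsin promoter. The control virus called DBD carried the repressor without its DNA-binding domain under the same promoter, and the control virus called Estop carried a stuffer sequence that encodes no protein. Mice were injected at 2 or 6 months of age, and the paradigms are named by age at injection and age at collection: 2M_6M, 2M_8M, 6M_8M, 6M_10M and 6M_12M, with 4, 6, 2, 4 and 6 months of treatment. Each group held 6 to 8 libraries, each from another mouse. Hemispheres were sequenced separately, so that 113 of the 120 mice gave 2 libraries with different viruses and 7 gave 1.

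Libraries were made from polyA RNA with a stranded protocol per the labels, and the submitters' processing notes name RSEM and the mouse build GRCm38, without versions. The deposited values are RSEM expected counts per gene, estimated counts that divide reads between transcripts and need not be whole (90.3% of the values were whole numbers). The annotation release and whether counting used the strand are not given in the sources used here, so values of antisense, overlapping and paralogous genes, among them the clustered protocadherins, are uncertain. A further deposited table was not used here. The count table holds 41135 entries, 6 of them for vector sequences, among them the repressor, the WPRE element shared by both protein-expressing viruses, EGFP and Estop. The 6 were left out of library sizes and tests (at most 0.669% of a library) and were used to check the labels. An added Htt entry, Htt.HD, was taken to be an expanded-allele sequence, as its reads were concentrated in zQ175 libraries. Gene symbols were taken from the reference annotation for 40254 of the 41129 gene entries, matched by identifier.

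Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM normalisation, robust quasi-likelihood F-test), with sex as a covariate. The 6 groups of a paradigm shared 1 fit, in which 15673, 15786, 16000, 15840 and 15523 genes were tested in the order of the paradigms above. Differences between paradigms came from 1 fit of all 30 groups with 16792 genes. The comparisons were genotype (zQ175 DBD minus WT DBD), repressor in zQ175 and in WT (nZFP minus DBD), genotype under repressor (zQ175 nZFP minus WT nZFP), control viruses (DBD minus Estop, per genotype), the interaction of repressor and genotype, and 5 differences of effects between paradigms. Adjusted p-values are Benjamini-Hochberg values from edgeR unless another test is named, and genes under 0.05 were counted as higher or lower. Fold changes are log2 with standard errors (SE), and levels are CPM from the cpm function of edgeR on the rounded gene counts, as mean ± SD. These choices, the gene lists and the rule for named genes were made before the data were examined. Simulated test data had 100 genes changed per fold size. For the repressor in zQ175 of 2M_6M, 40% and 74% of genes changed 1.25-fold and 1.5-fold were recovered (4.20% false calls). In 6M_12M it was 18% and 77% (5%), with 0 calls in an unchanged comparison. These rates describe simulated counts only.

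Named genes were Htt, then for the genotype and repressor comparisons the 8 higher and 8 lower genes that passed in the same direction in the most paradigms, ranked by mean log2 fold change, with a mean of at least 1 CPM and without predicted-gene symbols. Up to 4 members of each list with the smallest geometric mean p over the paradigms were added, up to 3 genes per direction for interactions and differences between paradigms, and 5 genes for the control viruses. A total of 30 lists were tested with camera (limma 3.58.1, preset correlation of 0.01, adjusted over lists within a comparison). They covered medium spiny neuron identity, direct and indirect pathway neurons, interneurons, potassium channels, immediate early genes, homeobox and Polycomb-repressed factors, clustered protocadherins, cholesterol synthesis, oxidative phosphorylation, heat shock, the p53 response, polyglutamine disease genes, astrocytes, reactive astrocytes, microglia, disease-associated microglia, interferon response, both classes of antigen presentation, lymphocytes, B cells, oligodendrocytes and their precursors, endothelial, mural, cortical, choroid plexus and ependymal cells, and pallidal and septal neurons. Counts of list members are given over all genes tested and, where stated, adjusted over the list alone. Each list call was repeated with the correlation estimated from the residuals. Marker lists describe transcripts of bulk tissue, not numbers of cells.

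A signature score was computed per library as the mean log2 CPM (TMM, prior count of 2) of genes higher in zQ175 minus that of genes lower in zQ175. The genes were chosen in the Estop libraries of the same paradigm and scored in the DBD and nZFP libraries, so that no library both chose and scored genes, although Estop libraries share mice with scored libraries. Reversal is the part of the DBD genotype difference removed under nZFP in percent, with a bootstrap interval over 10000 resamples of the libraries within groups. Scores and Htt.HD levels were compared with two-sided exact permutation tests. Intervals and tests took libraries as independent, and scores were therefore also fitted with the mouse as a block and taken from mice without an Estop library, a choice made after the data were seen.

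Library totals ran from 28044719 to 61355230 counts with a median of 37406090. At this depth a gene of 1 CPM rests on 28.0 to 61.4 counts, while the Htt.HD entry never exceeded 11.6 counts.

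The labels pair the libraries of a mouse. Residuals of libraries from the same mouse correlated on average by 0.0806, 0.267, 0.0541, 0.0634 and 0.316 over 22, 23, 24, 22 and 22 pairs, in the order of the paradigms, against -0.0276 to -0.0170 between mice. The mouse was therefore fitted as a block in an alternative, and its counts are given where they differed by over 1.5 times. Replicate numbers of the titles do not mark mice and were blocked in a separate alternative. Residuals of libraries of other mice with the same replicate number correlated on average by 0.0433, 0.0350, 0.0151, 0.0782 and 0.289, so that in 6M_12M libraries with the same number were nearly as alike as those of the same mouse. Other alternatives were DESeq2 1.42.0, its size factors, no count filter, no sex covariate, Estop in place of DBD, and other choices of the signature. After the data were seen, fits were added without 4 libraries whose vector entries contradict their labels, without 4 libraries that stood apart from the others of their paradigm (robust z above 6 on the first or second residual component), and with a length index as a covariate, the difference in mean log2 CPM between genes of at least 6000 bp and genes of at most 1500 bp. All libraries were kept under their labels in the main results, and an affected library is called the library labelled with its group.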

Results

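Striatal transcriptomes were measured in 233 libraries from 120 mice, in 30 groups formed by 5 paradigms of injection and collection age, 2 genotypes and 3 viruses. The zQ175 line is a knock-in model of Huntington's disease, and zQ175 mice here carried 1 expanded allele beside a normal Htt allele. Paradigms held 46, 47, 48, 46 and 46 libraries in the order 2M_6M, 2M_8M, 6M_8M, 6M_10M and 6M_12M, with 6 to 8 libraries per group. Lists of 5 values keep this order.

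Vector transcripts separated the viruses. The ZFP-30645 entry had a median of 595 CPM (98.7 to 1087) in the 77 nZFP libraries whose vector entries matched their label, against 8.26 CPM in 75 DBD and 10.6 CPM in 77 Estop libraries. WPRE, a viral RNA element, had a median of 1689 CPM under DBD, 931 CPM under nZFP and 36.9 CPM under Estop. The remaining 4 libraries went against their labels. In 6M_8M, the libraries labelled WT DBD R7 and R8 held 321 and 480 CPM of ZFP-30645, while the library labelled zQ175 nZFP R5 held 8.55 CPM. In 2M_6M, the library labelled WT DBD R6 held 3.73 CPM of the Estop entry and 59.2 CPM of WPRE. Values without these libraries are given where they ended a call, turned a direction or differed by over 1.5 times.

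Htt, the targeted gene (identifier ENSMUSG00000029104, chromosome 5: 34761740 to 34912534, GRCm38), was counted over both alleles and all cells of the tissue. In WT DBD libraries it stood at 122 ± 15.5 CPM (SD, n = 8) in 2M_6M and 114 ± 29.1 CPM (n = 8) in 2M_8M, and in zQ175 DBD libraries at 88.7 ± 22.9 CPM (n = 7) and 80.4 ± 20.4 CPM (n = 8). The genotype difference passed in these 2 paradigms, at log2 fold changes of -0.54 (SE 0.10, adjusted p = 7.8e-05) and -0.53 (SE 0.18, adjusted p = 0.030). In 6M_8M, 6M_10M and 6M_12M it was -0.22, -0.33 and -0.53 (adjusted p = 0.45, 0.15 and 0.064). Without the outlying libraries labelled WT DBD R2 and zQ175 nZFP R2 it was -0.46 in 6M_10M (adjusted p = 0.0010). With Estop in place of DBD it passed in 6M_10M (-0.60, adjusted p = 0.0067), with replicate numbers as a block in 6M_12M (-0.56, adjusted p = 2.70e-05), and with the length index as a covariate in both (-0.47 and -0.67, adjusted p = 8.04e-11 and 1.18e-11). Under nZFP against DBD in zQ175 mice, total Htt differed by -0.08, -0.32, -0.06, -0.45 and -0.07, with SE of 0.10 to 0.20, and did not pass in any paradigm (adjusted p = 0.57, 0.31, 1.0, 0.33 and 0.87). Without the libraries that contradict their labels the 6M_8M value was -0.22, and without outlying libraries those of 2M_6M and 6M_10M were -0.19 and -0.28, none passing. Against Estop in place of DBD the differences were -0.53, -0.34, -0.19, -0.52 and -0.32, and that of 2M_6M passed (adjusted p = 0.00021; 79.5 ± 7.26 CPM under nZFP, 120 ± 12.3 CPM under Estop, n = 8 each). With the length index as a covariate, Htt under nZFP against DBD passed in 2M_6M (-0.19, adjusted p = 0.023) and 6M_10M (-0.32, adjusted p = 0.00013). In WT mice nZFP against DBD gave 0.13, -0.51, 0.15, 0.20 and 0.06 without passing (0.038 in 6M_8M and 0.087 in 6M_10M without the libraries that contradict their labels or stood apart). The interaction of virus and genotype did not pass for Htt in any paradigm, except with the length index as a covariate in 2M_6M (-0.30, adjusted p = 0.018) and 6M_10M (-0.43, adjusted p = 0.0019).

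The Htt.HD entry received few reads, with a mean of 1.83, 4.00, 5.46, 4.31 and 4.36 counts in zQ175 DBD libraries and at most 11.6 counts in any library. Under nZFP the means were 0.648, 1.57, 0.527, 1.21 and 0.512 counts, which is 36.0%, 43.9%, 8.92%, 27.3% and 11.5% of the DBD level after division by library size. The fall passed a two-sided exact permutation test in 6M_8M (p = 0.000932, Benjamini-Hochberg 0.00233), 6M_10M (p = 0.00866, 0.0144) and 6M_12M (p = 0.000466, 0.00233), and not in 2M_6M (p = 0.144, 0.180) or 2M_8M (p = 0.180, 0.180). Without the libraries that contradict their labels the 6M_8M level was 10.2% of DBD (exact permutation p = 0.00233). DBD and Estop levels in zQ175 mice were not told apart in any paradigm (exact permutation p = 0.269, 0.915, 0.527, 0.237 and 0.406). At this number of reads, the percentages carry wide counting errors.

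**Figure D1:**
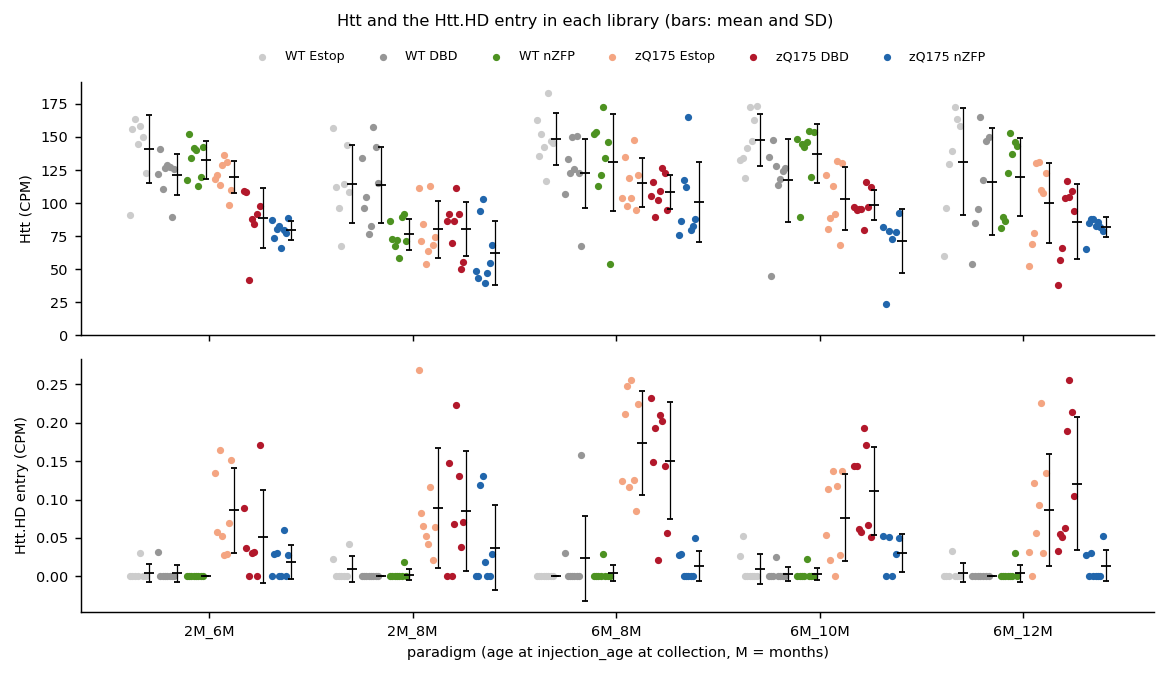
Htt (upper panel, CPM) and the Htt.HD entry (lower panel, CPM) in each library by paradigm and group, with points for libraries and bars for mean and SD. In zQ175 mice, mean Htt.HD levels under nZFP were below those under DBD, past the test in the 3 paradigms with injection at 6 months.

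The genotype comparison asked how the striatum of zQ175 mice differed from that of WT mice when both received DBD. Transcripts of embryonic transcription factors, low in WT mice, rose in zQ175 mice. Shox2, a homeobox factor, went from 0.105 ± 0.0443 CPM (n = 8) to 2.45 ± 0.379 CPM (n = 7) in 2M_6M and from 0.303 ± 0.117 CPM (n = 7) to 22.2 ± 3.47 CPM (n = 8) in 6M_12M. Its log2 fold changes were 4.44, 5.01, 2.30, 5.42 and 6.08 (SE 0.29, 0.32, 0.57, 0.23 and 0.22). Hoxc4, Onecut1 and Wt1 rose by 2.20 to 6.35 across paradigms. Nrn1, which encodes neuritin, rose by 1.00 in 2M_6M and by 4.23 in 6M_12M, and Dsp (desmoplakin), Sfmbt2 and Kazald1 rose by 1.20 to 2.56. Lower genes named by rule were Wnt8b, a Wnt ligand (-3.95 to -5.53), the glutathione peroxidase Gpx6 (-3.29 to -5.34), Abhd11os (-2.14 to -3.24) and the interleukin-2 receptor chain Il2rb (-1.78 to -3.18). With them went Vwa7 (-2.03 to -3.10), Mafa (-2.10 to -2.55), Sec14l3 (-1.84 to -2.65) and the serine protease Tmprss6 (-1.77 to -2.71). All 16 genes passed in all 5 paradigms. Without the libraries that contradict their labels, 6M_8M values were 5.75 for Shox2, 5.17 for Hoxc4, 4.70 for Onecut1, 4.86 for Wt1, 2.52 for Dsp, 2.35 for Sfmbt2 and 2.11 for Kazald1.

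Markers of medium spiny neurons, the projection neurons of the striatum, were lower in zQ175 mice. Of 30 shared identity genes, 26, 24, 25, 25 and 24 were lower, and 27, 24, 27, 27 and 26 when adjusted over the list alone. The list was lower by camera in every paradigm, also with an estimated correlation (adjusted p = 0.000207, 5.29e-05, 0.0183, 8.91e-06 and 5.11e-05). Scn4b, a sodium channel subunit, fell by 1.52, 1.47, 1.35, 1.64 and 1.66 (SE 0.07 to 0.17), and the phosphodiesterase Pde1b fell by 0.55 to 0.81. Rgs4 fell by 1.05, 1.12, 0.85 and 1.20 in the paradigms before 6M_12M and was lower there too. Ppp1r1b, which encodes DARPP-32, fell by 0.67 to 0.96. Of 9 indirect pathway genes, 6, 5, 5, 5 and 5 were lower (adjusted p = 0.000138, 1.68e-05, 0.0167, 0.000129 and 0.000107 with an estimated correlation; 6, 6, 5, 6 and 5 adjusted over the list alone). Penk, the enkephalin precursor, went from 1561 ± 101 CPM (n = 8) to 706 ± 178 CPM (n = 7) in 2M_6M, and fell by 1.05 to 1.52 on the log2 scale across paradigms. The adenosine receptor Adora2a fell by 0.75 to 1.06, Upb1 by 1.62 to 2.59 and Gpr6 by 0.64 to 1.10. The direct pathway list did not pass in any paradigm (adjusted p = 0.78, 0.34, 0.11, 0.24 and 0.081), and its 10 members went both ways, with 4, 2, 0, 1 and 0 higher and 2, 3, 2, 3 and 4 lower (4, 3, 0, 1 and 1 higher and 2, 3, 2, 4 and 4 lower adjusted over the list alone). The dopamine receptor Drd1 fell by 0.71 to 0.93 and the muscarinic receptor Chrm4 by 0.71 to 0.97. Eya1 rose by 0.47, 0.39 and 0.40 in 2M_6M, 2M_8M and 6M_10M.

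Of the measured homeobox and Polycomb-repressed factors, genes of embryonic development, 7 of 13, 12 of 18, 9 of 18, 17 of 22 and 16 of 22 were higher (adjusted p = 0.00736, 0.000964, 0.0124, 8.6e-06 and 1.18e-05 with an estimated correlation). Adjusted over the list alone, 7, 12, 12, 17 and 17 were higher. Clustered protocadherins are cell adhesion genes in tandem arrays, and reads can be shared between copies. Of 24 members, 14, 18, 13, 15 and 16 were higher, and 15, 19, 18, 17 and 19 adjusted over the list alone. Among them were Pcdhb3 at 0.66 to 1.29 and Pcdhb9 at 0.58 to 0.76. This list passed camera in every paradigm, and with an estimated correlation in 2M_8M (adjusted p = 0.00407) and 6M_12M (0.0290) but not in 2M_6M, 6M_8M and 6M_10M (adjusted p = 0.141, 0.0969 and 0.134). Of 14 potassium channel genes, 9, 5, 6, 9 and 8 were lower (11, 5, 8, 10 and 9 adjusted over the list alone), among them Kcnip2 (-0.54 to -0.93) and Kcnk2 (-0.41 to -0.61). Camera called this list in every paradigm, and adjusted p was 0.00798, 0.139, 0.0462, 0.0601 and 0.0483 with an estimated correlation. Immediate early genes, induced by neuronal activity, were lower for 7, 4, 3, 7 and 2 of 18 members (7, 7, 3, 9 and 2 adjusted over the list alone). Camera calls in 2M_6M, 6M_8M and 6M_10M were lost with an estimated correlation (adjusted p = 0.660, 0.628 and 0.683). Egr2 fell by 1.67 to 2.39 in all paradigms, while Nr4a2 rose by 0.77, 1.52, 1.29 and 2.18 in those other than 6M_8M, and by 1.95 there without the libraries that contradict their labels.

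In total, 4497, 2951, 1460, 3837 and 2838 genes passed in the genotype comparison, of which 2694, 1472, 636, 1890 and 1419 were higher and 1803, 1479, 824, 1947 and 1419 lower. 335 genes were higher and 514 lower in all 5 paradigms, against 0.107 and 0.0957 from independent lists of these sizes. Replicate numbers as a block gave 4811 in 6M_12M. Without the 3 libraries that contradict their labels, 2708 genes passed in 6M_8M.

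**Figure D2:**
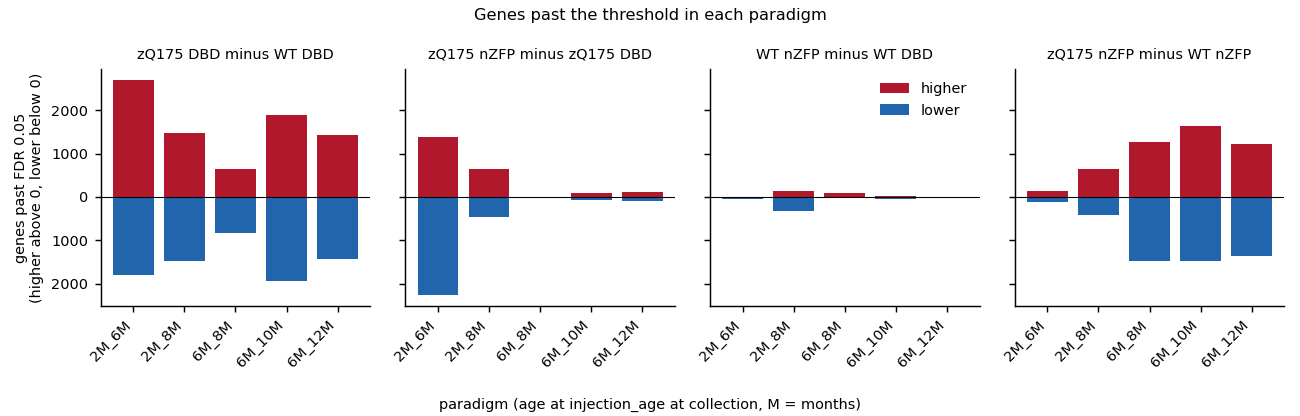
Number of genes past an adjusted p of 0.05 in 4 comparisons (panels) by paradigm, with higher genes above 0 and lower genes below 0. Counts for nZFP against DBD in zQ175 mice were 3633 and 1114 after injection at 2 months and 18, 154 and 194 after injection at 6 months. The mouse as a block gave 732 in 2M_6M, and replicate numbers as a block gave 3035 in 6M_12M.

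The effect of the repressor in zQ175 mice was measured as nZFP against DBD. Genes of medium spiny neurons that were lower in zQ175 mice rose under nZFP. Scn4b rose by 1.31, 0.99, 0.59 and 0.78 in 2M_6M, 2M_8M, 6M_10M and 6M_12M (SE 0.12, 0.16, 0.08 and 0.14), and stood at 0.62 in 6M_8M (SE 0.17, adjusted p = 0.18). Penk reached 1153 ± 134 CPM (n = 8) under nZFP in 2M_6M, and its log2 change of 0.72, 0.97, 0.53 and 0.37 passed in those 4 paradigms. So did those of Adora2a (0.81, 0.82, 0.47 and 0.52), the calcium sensor Hpca (0.72, 0.54, 0.26 and 0.34), Kcnk2 (0.43, 0.43, 0.34 and 0.28) and Kcnip2 (0.38, 0.40, 0.25 and 0.30). Drd1 rose by 0.49, 0.43 and 0.26 in 2M_6M, 2M_8M and 6M_12M. Developmental factors went the other way: Shox2 fell by 2.38, 1.67, 1.20 and 1.27 in the paradigms other than 6M_8M, to 0.456 ± 0.2 CPM (n = 8) in 2M_6M and 9.28 ± 1.52 CPM (n = 8) in 6M_12M. Pou4f1 (-1.16 to -2.06) and Nrn1 (-0.98 to -1.42) were lower in the same paradigms, Hoxc5 in 2M_8M and 6M_10M (-1.91 and -1.11) and in 6M_12M, and Neurod2 in 2M_8M and, at -1.32, in 6M_12M.

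By the rule for named genes, the higher genes were led by Abhd11os, at 2.02, 2.88, 1.31, 1.71 and 1.37 (SE 0.20 to 0.26), and the calcium-binding protein gene Necab2, at 0.65, 0.60, 0.42, 0.62 and 0.61 (SE 0.06 to 0.10), both past the threshold in all 5 paradigms. Past it in all but 6M_8M were Sec14l3 (0.71 to 2.01), Fst, which encodes the activin antagonist follistatin (1.14 to 1.90), and Upb1 (0.83 to 1.29). Ddit4l, an inhibitor of mTOR signalling (0.55 to 1.55), and the phosphatase Ptpn7 (0.73 to 1.23) passed in these too. Among lower genes, Tceal6 fell by 1.78, 1.54, 1.39, 1.93 and 2.02 (SE 0.17 to 0.28), Mzt2 by 0.78 to 1.47 and Impdh1, an enzyme of guanine nucleotide synthesis, by 0.89 to 1.36. The kinase Stk32c fell by 0.85 to 1.32, the transcription factor Dach1 by 0.59 to 1.43, the mitochondrial GTPase Noa1 by 0.50 to 0.89 and Eid2b by 0.44 to 0.71 in all 5 paradigms. Nap1l3 fell by 1.88, 1.91 and 1.99 in 2M_6M, 6M_10M and 6M_12M, was lower in 2M_8M too, and stood at -1.23 in 6M_8M (SE 0.29, adjusted p = 0.075; -1.56 and 0.00037 without the libraries that contradict their labels). With the mouse as a block, the 6M_8M calls of Abhd11os, Tceal6, Impdh1, Stk32c and Dach1 were lost (adjusted p = 0.97, 0.20, 0.12, 0.19 and 0.23), as were the 6M_10M calls of Sec14l3, Hpca, Penk and Pou4f1 (0.18, 0.17, 0.081 and 0.099). Without the 2 outlying libraries of 6M_10M, Penk stood at 0.29 there (adjusted p = 0.072), Abhd11os at 1.14, and Drd1 passed at 0.25.

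Among the lists, shared medium spiny neuron identity rose for 26, 19, 0, 9 and 6 of 30 members, or 26, 23, 8, 14 and 21 adjusted over the list alone (adjusted p = 0.00207, 0.000892, 0.137, 0.0203 and 0.00545 with an estimated correlation). Arpp21, a phosphoprotein gene of this list, fell by 0.95, 0.60 and 0.94 in 2M_6M, 2M_8M and 6M_10M, was lower in 6M_12M too, and fell by 0.90 in 6M_8M without the libraries that contradict their labels. Indirect pathway genes rose for 7, 5, 0, 3 and 3 of 9 members, or 7, 5, 4, 4 and 6 adjusted over the list alone (adjusted p = 0.000326, 0.000116, 0.0876, 0.00768 and 0.000213 with an estimated correlation). Potassium channels rose for 10, 3, 0, 2 and 2 of 14 members, or 10, 4, 0, 3 and 3 adjusted over the list alone. This call held with an estimated correlation in 2M_6M (adjusted p = 0.00786) and 6M_12M (0.0423) but not in 2M_8M, 6M_8M and 6M_10M (0.337, 0.0876 and 0.431). Homeobox and Polycomb-repressed factors fell for 7, 9, 0, 5 and 6 members, or 7, 11, 0, 6 and 11 adjusted over the list alone (adjusted p = 0.0837, 0.00999, 0.137, 0.0217 and 0.0200 with an estimated correlation). Clustered protocadherins fell for 9, 16, 0, 0 and 4 of 24 members, or 9, 20, 0, 2 and 6 adjusted over the list alone, Pcdhb20 among them (-0.81 and -0.68 in 2M_6M and 2M_8M). This call held with an estimated correlation in 2M_8M (adjusted p = 0.000892) but not elsewhere (0.493, 0.393, 0.358 and 0.271). With the mouse as a block, 22, 24, 0, 4 and 13 identity genes, 5, 5, 0, 2 and 5 indirect pathway genes and 5, 5, 0, 2 and 2 potassium channels were higher, and 6, 9, 0, 2 and 9 homeobox factors and 5, 13, 0, 1 and 5 protocadherins lower. The block ended the potassium channel call in 6M_10M (adjusted p = 0.452), and with an estimated correlation the identity and indirect pathway calls there (0.517 and 0.0910). Homeobox factors in 2M_6M and protocadherins in 6M_12M held with the block and an estimated correlation (0.0343 and 0.0423). Against Estop, 20, 18, 0, 0 and 1 identity genes, 5, 5, 0, 2 and 2 indirect pathway genes and 5, 3, 0, 0 and 0 potassium channels were higher, and 6, 11, 0, 7 and 11 homeobox factors lower. Calls of Kcnk2 and Kcnip2 in 6M_10M and 6M_12M ended. Of the protocadherins, 12, 11, 1, 2 and 0 were lower and 1, 1, 0, 1 and 4 higher, and camera did not call them in 6M_8M, 6M_10M and 6M_12M (adjusted p = 0.251, 0.140 and 0.693). Against Estop, the identity list did not hold with an estimated correlation in 6M_8M, 6M_10M and 6M_12M (adjusted p = 0.538, 0.295 and 0.157), nor did potassium channels in 6M_12M (0.0520), whose camera call in 6M_10M was lost (0.0858). Homeobox factors and protocadherins of 2M_6M held there (0.00699 and 0.0348).

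In total, 3633, 1114, 18, 154 and 194 genes passed, of which 1379, 656, 7, 89 and 105 were higher and 2254, 458, 11, 65 and 89 lower, and 2 were higher and 8 lower in all 5 paradigms. With the mouse as a block the counts were 732 (462 higher), 1097, 5, 101 and 360, and with replicate numbers as a block 3035 genes passed in 6M_12M. The library labelled zQ175 DBD R3 stood apart in 2M_6M, with low counts of long genes (length index 1.13), and without it 2165 genes passed (1174 higher). Without the 3 libraries that contradict their labels, 29 genes passed in 6M_8M. Against Estop in place of DBD, 1157 genes passed in 2M_6M (594 higher), so that the excess of lower genes in 2M_6M was not kept with the mouse block, without that library or against Estop. In 2M_6M, oxidative phosphorylation genes were lower for 24 of 77 members (33 adjusted over the list alone) and ependymal genes for 6 of 7 (7 adjusted over the list alone), calls lost with an estimated correlation (adjusted p = 0.715 and 0.622). Without the library labelled zQ175 DBD R3, 0 and 1 of these members were lower.

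**Figure D3:**
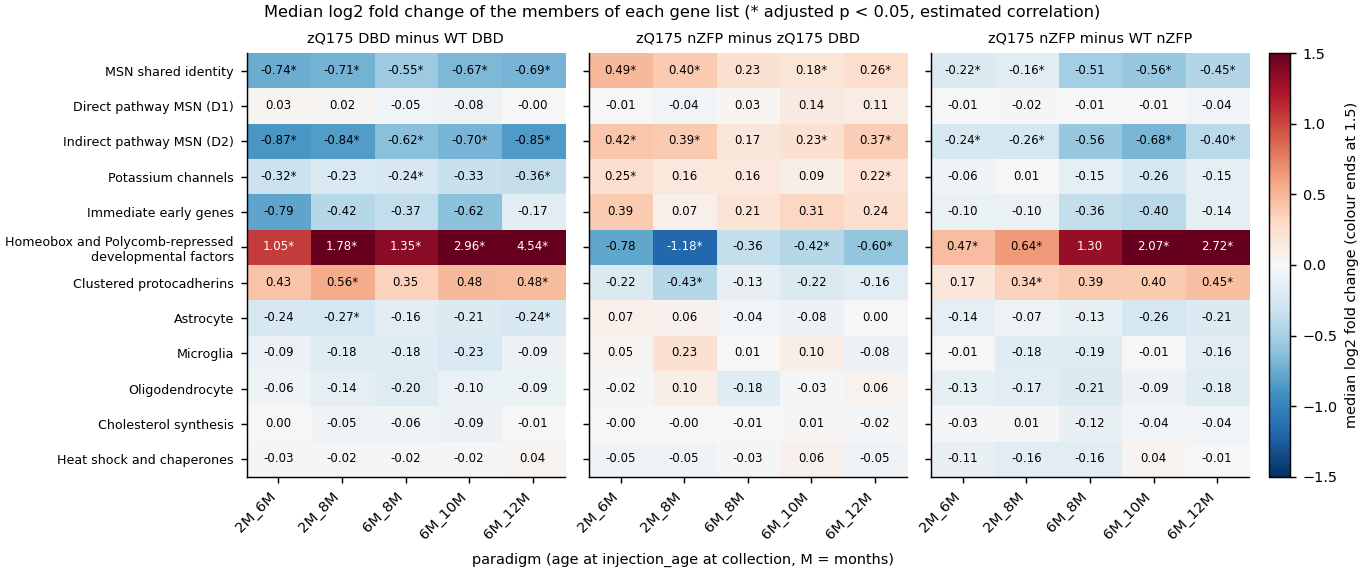
Median log2 fold change of the members of 12 gene lists (rows) in each paradigm (columns) for 3 comparisons (panels), with the value in each cell, colour from -1.5 to 1.5, and a star where adjusted p was below 0.05 with an estimated correlation. The identity and indirect pathway lists had medians below 0 for genotype and above 0 for nZFP, and the homeobox list the reverse.

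How far nZFP moved the genotype signature was measured with scores from genes chosen in Estop libraries. Genes higher in zQ175 numbered 1582, 1326, 1292, 1915 and 1316 and genes lower 1454, 1346, 1062, 1763 and 1384. Scores in zQ175 DBD libraries were -1.05, -0.994, -0.572, -1.17 and -0.957, against -1.92, -1.99, -1.30, -2.08 and -2.10 in WT DBD libraries, and moved to -1.52, -1.504, -0.800, -1.31 and -1.19 under nZFP. This is a reversal of 53.6% (95% interval 46.6 to 60.5) in 2M_6M, 51.1% (44.0 to 58.9) in 2M_8M, 31.2% (12.1 to 69.3) in 6M_8M, 14.7% (6.63 to 20.8) in 6M_10M and 20.6% (18.0 to 23.3) in 6M_12M. Each shift passed a two-sided exact permutation test (p = 0.000155, 0.000155, 0.000466, 0.00466 and 0.000155, where 0.000155 is the smallest that 8 against 7 or 8 libraries can give). WT nZFP and WT DBD scores were not told apart after adjustment (exact permutation p = 0.760, 0.550, 0.0493, 0.401 and 0.549, Benjamini-Hochberg 0.246 for 6M_8M). Without the 3 libraries that contradict their labels the 6M_8M reversal was 13.5% (8.36 to 18.8, exact permutation p = 0.000932). With the mouse as a block on the scores of the zQ175 libraries, reversal was 54.5%, 50.9%, 32.9%, 12.3% and 20.9%. In mice that gave no Estop library, so that no mouse gave both an Estop and a scored library, it was 46.6%, 47.9%, 56.7%, 6.96% and 20.3%, and scores were lower under nZFP than under DBD in 3 of 3, 4 of 4, 4 of 4, 2 of 3 and 4 of 4 zQ175 mice with both. The 6M_8M value of 56.7% includes the 3 libraries that contradict their labels.

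Reversal differed between injection ages at matched months of treatment. On a scale of 0 for WT DBD and 1 for zQ175 DBD, zQ175 nZFP libraries stood at 0.464 ± 0.0919 (n = 8) in 2M_6M and 0.853 ± 0.0920 (n = 6) in 6M_10M, both with 4 months of treatment (exact permutation p = 0.000333, Benjamini-Hochberg 0.000666). With 6 months of treatment they stood at 0.489 ± 0.110 (n = 8) in 2M_8M and 0.794 ± 0.0265 (n = 8) in 6M_12M (exact permutation p = 0.000155, Benjamini-Hochberg 0.000622). Scores of 0.688 ± 0.379 (n = 8) in 6M_8M were not told apart from those in 6M_12M (exact permutation p = 0.827) or in 2M_8M (exact permutation p = 0.176, Benjamini-Hochberg 0.235). With the signature from DBD libraries scored with Estop, the latter p was 0.0390 (exact permutation test, Benjamini-Hochberg 0.0520). Without the libraries that contradict their labels, 6M_8M minus 6M_12M was 0.0715 (exact permutation test, Benjamini-Hochberg 0.00311) and 2M_8M minus 6M_8M was -0.376 (0.000466). Within each pair of equal treatment, mice injected at 6 months were also older at collection, while 2M_8M and 6M_8M mice were of equal age at collection but differed in months of treatment. Each paradigm was also a separate cohort, so that these factors were not separated.

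**Figure D4:**
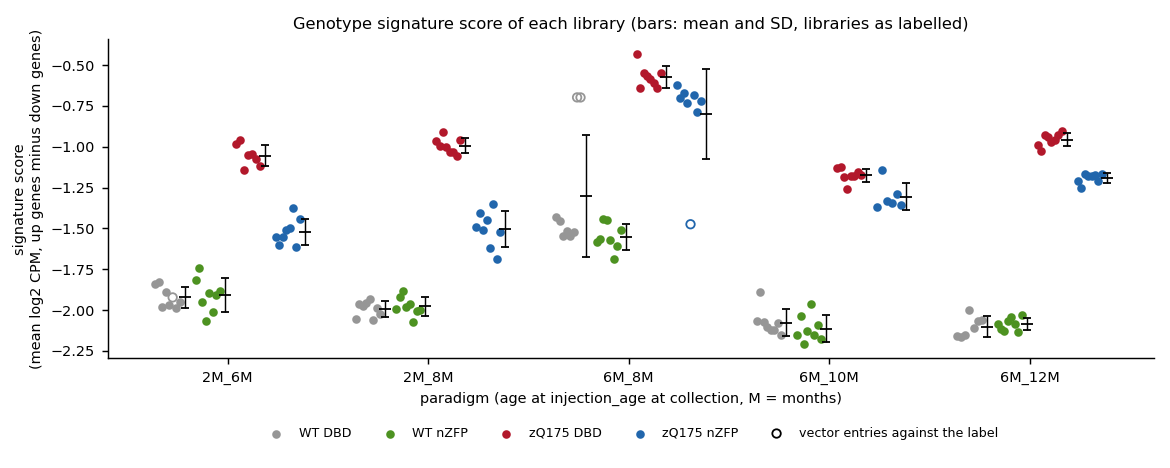
Signature score of each DBD and nZFP library (points; mean log2 CPM of genes higher minus genes lower in zQ175) by paradigm and group, with bars for mean and SD and open circles for libraries whose vector entries go against their label. Mean scores of zQ175 nZFP libraries lay between those of zQ175 DBD and WT DBD in every paradigm, nearer to zQ175 DBD in 6M_8M, 6M_10M and 6M_12M.

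The genotype lists chosen in Estop libraries came from the same fit as the repressor comparison, but their contrasts share no library. With these lists, 536 of 1582 genes higher in zQ175 fell under nZFP in 2M_6M and 647 of 1454 genes lower in zQ175 rose, against 228 and 128 from independent lists, while 6 and 19 moved in the direction of genotype (139 and 209 from independent lists). In 2M_8M, 302 of 1326 fell and 471 of 1346 rose, against 38.5 and 55.9. The numbers were 2 and 6 in 6M_8M (0.888 and 0.465 from independent lists), 30 and 70 in 6M_10M (7.86 and 9.91) and 51 and 92 in 6M_12M (7.55 and 9.36). In the direction of genotype, 2 and 5, 0 and 0, 2 and 10, and 3 and 6 genes moved in these 4 paradigms, against 55.1 and 39.1, 0.565 and 0.730, 10.8 and 7.23, and 8.90 and 7.94.

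The genotype difference under repressor, zQ175 nZFP against WT nZFP, described what remained. The developmental factors Onecut1 (2.61, 3.21, 4.59, 5.56 and 5.59), Hoxc4 (2.58 to 5.30), Wt1 (3.11 to 4.73) and Shox2 (2.47, 2.75, 4.48, 4.91 and 4.69) were higher in zQ175 mice in all 5 paradigms, as were Dsp (1.31 to 2.83), Sfmbt2 (0.96 to 2.42), Kazald1 (0.65 to 2.51) and Fam196b (0.72 to 2.08). Lower in all 5 paradigms were Tmprss6 (-1.04 to -2.35), Cpne9 (-0.91 to -1.84), the endopeptidase Phex (-0.83 to -1.88), Sec14l3 (-0.52 to -2.06), Ddit4l (-0.64 to -1.74), Plk5 (-0.65 to -1.41), the G protein-coupled receptor Mas1 (-0.61 to -1.48) and Clspn (-0.58 to -1.41). Penk stood at -0.47, -0.56, -1.06, -0.90 and -1.12, Pde1b at -0.28 to -0.64, Rgs4 at -0.56 to -1.09, Drd1 at -0.18 to -0.71 and Adora2a at -0.27 to -0.74, all passing. Scn4b passed at -0.41, -1.14, -1.30 and -1.15 and stood at -0.41 in 2M_8M (adjusted p = 0.10). Htt was lower by -0.75, -0.99 and -0.65 in 2M_6M, 6M_10M and 6M_12M, and stood at -0.34 in 2M_8M (adjusted p = 0.26) and -0.42 in 6M_8M (adjusted p = 0.055; -0.59 and 0.0014 without the libraries that contradict their labels).

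Shared identity genes were lower for 10, 12, 24, 25 and 20 of 30 members, or 19, 17, 26, 26 and 22 adjusted over the list alone (adjusted p = 0.00368, 0.0463, 0.0886, 3.16e-05 and 0.00236 with an estimated correlation). Indirect pathway genes were lower for 4, 4, 5, 6 and 5 of 9 members, or 4, 5, 5, 6 and 5 adjusted over the list alone (0.00368, 0.0463, 0.0886, 0.000402 and 0.0192). Homeobox and Polycomb-repressed factors were higher for 5, 7, 11, 16 and 16 members, or 5, 10, 11, 16 and 18 adjusted over the list alone (0.00109, 0.0463, 0.0886, 2.86e-05 and 0.000205). Clustered protocadherins were higher for 3, 14, 16, 15 and 16 of 24 members, or 6, 19, 19, 16 and 17 adjusted over the list alone, with Pcdhb3 at 0.44 to 1.24 (adjusted p = 0.109, 0.00938, 0.0886, 0.317 and 0.0242 with an estimated correlation). In total, 241, 1053, 2731, 3097 and 2589 genes passed (137, 640, 1263, 1627 and 1231 higher), of which 67 were higher and 49 lower in all 5 paradigms. Replicate numbers as a block gave 6655 in 6M_12M. Without the library labelled zQ175 DBD R3, which is in the same fit, 623 genes passed in 2M_6M. In 2M_6M, 123 of 137 higher and 99 of 104 lower genes also passed in the same direction in the genotype comparison under DBD, and in 6M_12M 847 of 1231 and 876 of 1358.

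The repressor was also compared with DBD in WT mice, which carry no expanded allele. Lower in all 5 paradigms were Klf14, a Kruppel-like factor (-1.09, -1.33, -1.67, -1.45 and -1.22), and the imprinted gene Mkrn3 (-0.96, -1.02, -0.87, -0.98 and -0.83). In the 4 paradigms other than 6M_8M, Arpp21 fell by 1.40, 0.93, 1.43 and 1.43 (SE 0.12, 0.14, 0.09 and 0.16), from 1860 ± 126 CPM (n = 8) to 704 ± 243 CPM (n = 8) in 2M_6M. Gpx6 fell by 1.52 to 2.22, Nap1l3 by 1.26 to 1.89, Tceal6 by 1.38 to 1.85, Impdh1 by 1.13 to 1.31 and the calcium pump Atp2b3 by 0.89 to 1.55. In 6M_8M these stood at -0.58, -0.91, -1.03, -0.88, -0.57 and -0.73, and passed at -0.86, -1.32, -1.24, -1.12, -0.76 and -0.91 without the libraries that contradict their labels. Necab2 rose in all 5 paradigms, by 0.41, 0.39, 0.54, 0.39 and 0.43. The purinergic receptor gene P2ry1 rose by 0.65 to 0.71 in 2M_8M, 6M_10M and 6M_12M, and Habp4 (0.21 to 0.31) and Rab15 (0.15 to 0.28) rose in 3 paradigms each. Shox2 fell by 3.04 in 6M_8M and stood at 0.41 (adjusted p = 0.65) without the libraries that contradict their labels.

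Against Estop instead of DBD, the direction of Klf14 turned (1.80, 1.64, 0.33, 1.46 and 1.80), as did that of Mkrn3 (0.23, 0.26, 0.41, 0.36 and 0.45, not passing). Counts against Estop were 92, 153, 7 and 56 in 2M_6M, 2M_8M, 6M_8M and 6M_12M. The mouse block ended the WT calls of Klf14 in 2M_6M and 6M_8M (adjusted p = 0.058 and 0.30), Mkrn3, Habp4, Rab15, Abhd11os and Shox2 in 6M_8M (0.22, 0.090, 0.33, 0.17 and 0.50), Habp4 in 2M_6M (0.17), and Atp2b3 in 2M_6M and 6M_10M (0.076 and 0.25). Shared identity genes were lower for 1, 1, 0, 1 and 1 of 30 members, which was Arpp21 in each case. Protocadherins were lower for 0, 9, 1, 1 and 0 of 24 members (0, 15, 8, 1 and 1 adjusted over the list alone), with Pcdhb20 at -0.33 and -0.30 in 2M_8M and 6M_10M. Camera called protocadherins in the paradigms other than 2M_6M (adjusted p = 0.0622, 0.664, 0.935 and 0.780 with an estimated correlation). Of 30 lists, 0, 4, 8, 3 and 4 passed camera and 0 in any paradigm with an estimated correlation, while with the mouse as a block the astrocyte list was lower in 6M_10M also with an estimated correlation (adjusted p = 0.00258). In total, 42, 470, 93, 76 and 37 genes passed (5, 148, 83, 29 and 5 higher), and 32, 221, 3, 44 and 63 with the mouse as a block. Replicate numbers as a block gave 728, 125 and 73 in 2M_8M, 6M_10M and 6M_12M. Without outlying libraries 74 passed in 2M_6M and 157 in 6M_10M.

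Genes that fell under nZFP in WT mice overlapped with those that fell in zQ175 mice. With zQ175 nZFP set against Estop, so that the comparisons had no control virus in common, 27 of 37 genes lower in WT were lower in zQ175 in 2M_6M, 28 of 322 in 2M_8M, 0 of 10 in 6M_8M, 25 of 47 in 6M_10M and 18 of 32 in 6M_12M, against 1.33, 7.14, 0.246 and 0.280 from independent lists in the paradigms other than 6M_8M.

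**Figure D5:**
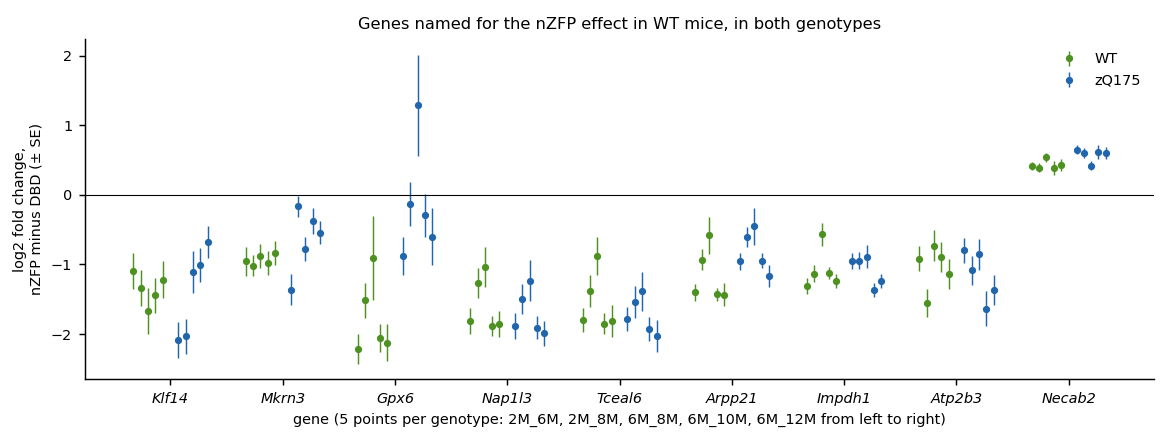
Log2 fold change of nZFP against DBD (± SE) in WT and zQ175 mice for 9 genes named in the WT comparison, with 5 points per genotype for the paradigms. Nap1l3, Tceal6, Arpp21, Impdh1 and Atp2b3 were below 0 in both genotypes and Necab2 above 0, while Gpx6 was at -2.22 in WT and -0.88 in zQ175 in 2M_6M.

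The control viruses differed from each other in a few genes. Under DBD against Estop, Klf14 rose by 2.22 to 3.13 in zQ175 and by 1.99 to 3.02 in WT mice, and Tcfl5, a transcription factor of the male germ line, by 1.38 to 2.03 and by 2.24 to 3.31, in all 5 paradigms. In WT mice of 2M_6M, Tcfl5 went from 0.675 CPM under Estop to 4.61 CPM under DBD and was at 5.59 CPM under nZFP, and Mkrn3 went from 1.47 to 3.38 CPM and was at 1.73 CPM under nZFP. Nup62cl (2.47 to 4.33) and Mkrn3 (1.19 to 1.33) rose in WT mice in all paradigms, and Pcdhb18 (0.56 to 0.86) in zQ175 mice. Pcdhb8 rose by 0.81, 1.41, 1.48 and 1.49 and Fbxl16, an F-box protein gene, fell by 0.50, 0.38, 0.32 and 0.47 in zQ175 mice in the paradigms other than 6M_8M. Htt was lower under DBD than under Estop in zQ175 mice of 2M_6M (-0.45, SE 0.10, adjusted p = 0.019), and this call was lost without the library labelled zQ175 DBD R3 (-0.34, adjusted p = 0.053) and with the mouse as a block (-0.42, adjusted p = 0.096). The block also ended the calls of Pcdhb8 in 2M_6M (0.20), Pcdhb18 and, in WT, Nup62cl in 6M_8M (0.057 and 0.13) and Fbxl16 in 6M_10M (0.41).

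Counts were 705, 29, 9, 37 and 45 in zQ175 and 17, 31, 30, 106 and 26 in WT mice. With the mouse as a block they were 69 (11 higher), 33, 5, 10 and 173 in zQ175 and 15, 78, 15, 50 and 59 in WT mice. In 2M_6M, 523 of the 705 genes in zQ175 were higher, and 79 genes (20 higher) passed without the library labelled zQ175 DBD R3 and 2 in a fit of these 2 groups alone. Oxidative phosphorylation genes were higher for 37 of 77 members (64 adjusted over the list alone, adjusted p = 0.872 with an estimated correlation) and for 0 without that library. In WT mice 46 genes passed in 2M_6M without it. Without outlying libraries 78 genes in zQ175 and 249 in WT passed in 6M_10M, and 15 in zQ175 in 6M_8M without the libraries that contradict their labels. Homeobox and Polycomb-repressed factors were lower under DBD than under Estop in zQ175 mice of 6M_12M for 7 of 22 members (10 adjusted over the list alone), also with an estimated correlation (adjusted p = 5.34e-06) and with the mouse as a block (0.000919). Held there with an estimated correlation, but not with the block, were cortical genes (2 of 8 lower, 4 adjusted over the list alone, 0.00187, block 0.0608), protocadherins (2 higher and 1 lower of 24, 10 and 2 adjusted over the list alone, 0.0259, block 0.112) and shared identity genes (0 of 30 lower, 0.0483, block 0.112). With the block, homeobox factors (lower, 0.0232) and astrocyte genes (higher, 0.0308) held in 6M_10M.

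The identity list was lower under DBD than under Estop by camera in all 5 paradigms, in zQ175 mice (4, 0, 0, 1 and 0 of 30 members lower, or 11, 2, 0, 3 and 1 adjusted over the list alone) and in WT mice (0, 0, 0, 1 and 0, or 0, 1, 0, 8 and 0). With an estimated correlation, adjusted p was 0.592, 0.712, 0.943 and 0.0799 in zQ175 mice before 6M_12M, and 0.417, 0.771, 0.807, 0.280 and 0.466 in WT mice. The list call in WT mice of 6M_8M was lost with the mouse as a block (0.0610), and the reactive astrocyte list of WT mice of 6M_10M (higher, 0.415 with an estimated correlation) held with it (0.00830).

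Whether the repressor acted differently in the genotypes was tested as an interaction. Larger rises in zQ175 than in WT mice were found for Ddit4l (1.47, SE 0.13, adjusted p = 4.5e-10 in 2M_6M, then 1.31 in 2M_8M and 0.60 in 6M_10M) and the apoptosis gene Hrk (1.02 and 1.02 in 2M_6M and 2M_8M). The same held in 2M_6M and 2M_8M for the kinase Rps6ka4 (0.81 and 0.68), Wnt8b (3.03 and 3.84), Upb1 (1.07, 1.26 and, in 6M_10M, 1.44) and Fst (0.98, 1.30 and 1.18). Negative interactions passed for Stmn2, a regulator of microtubules (-0.64 and -0.62 in 2M_6M and 2M_8M), Gprasp2 (-0.46 and -0.34), Pcdhb20 (-0.63 and -0.35) and Slc5a5 (-0.62 and -0.97). Pcdh20 (-0.90, -0.93 and -0.57) and Gng4 (-0.53, -0.52 and -0.47) also passed in 6M_10M. Among medium spiny neuron genes, Scn4b (1.11 and 1.06), Ppp1r1b (0.64 and 0.52), Drd1 (0.52 and 0.54), Adora2a (0.70 and 0.63) and Penk (0.70 and 0.81) had positive interactions in 2M_6M and 2M_8M.

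Interactions passed for 19, 18, 0, 0 and 0 of 30 shared identity genes (25, 23, 0, 10 and 1 adjusted over the list alone), and the list held with an estimated correlation in 2M_6M, 2M_8M and 6M_12M (adjusted p = 0.000809, 0.000111 and 0.00719). Over all genes 512 and 314 passed in 2M_6M and 2M_8M (327 and 231 positive) and 8 in 6M_10M. Replicate numbers as a block gave 16 in 6M_10M and 83 in 6M_12M. In 6M_8M and 6M_12M edgeR called 0 genes, with 710 and 643 at an unadjusted p under 0.05, and DESeq2 called 0 and 11. With the mouse as a block the counts were 107, 643, 0, 1 and 15, and 6, 21, 0, 0 and 2 identity genes passed. The 6M_10M calls of Ddit4l, Fst, Pcdh20 and Gng4 were lost under it (adjusted p of 0.56 each), as were those of Slc5a5 (0.14) and Ppp1r1b (0.055) in 2M_6M and Pcdhb20 in 2M_8M (0.065). Fst and Gng4 were lost in 6M_10M without outlying libraries (0.070 and 0.050), and Slc5a5 without the library labelled WT DBD R6 (0.055), while Scn4b (0.48) and Drd1 (0.34) passed in 6M_10M without outlying libraries.

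Effects were then compared between paradigms in 1 fit of all groups. The repressor effect in zQ175 mice was larger in 2M_8M than in 6M_12M, at 6 months of treatment each, for Plk5 (difference 0.96, SE 0.17, adjusted p = 0.000456), Zfp180 (0.62) and Hrk (0.69), and lower for Pcdhb20 (-0.47), among 14 genes (12 higher). Between 2M_8M and 6M_8M, both collected at 8 months, 9 genes differed, among them Fst (1.43, SE 0.27, adjusted p = 0.00362), Gadd45a (0.91), Il2rb (1.91) and Pcdhb20 (-0.49). Without the libraries that contradict their labels these counts were 71 and 60. Between 6M_8M and 6M_12M 1 gene passed in edgeR, the immunoglobulin segment Ighv1-69 (-11.07), with 606 at an unadjusted p under 0.05, and 10 in DESeq2. For 2M_6M against 6M_10M, 2059 genes passed (431 higher), with Syt9 at 0.96 (SE 0.15, adjusted p = 6.22e-07), Rps6ka4 at 0.62, Slc9a5 at 0.61 and Rad9b at -3.12. Without outlying libraries 11 genes passed, all higher, Slc9a5 (adjusted p = 0.057) and Rad9b (0.99) not among them, and 12 with Estop in place of DBD (9 higher). With the length index as a covariate 662 passed (348 higher).

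The genotype effect itself differed between 2M_6M and 6M_12M for 40 genes (22 higher). The difference, 2M_6M minus 6M_12M, was negative for Nrn1 (-3.25, SE 0.42, adjusted p = 3.56e-09), the ephrin receptor gene Epha10 (-0.98) and Nxph4 (-1.20). It was positive for Cdhr1 (1.02) and Clec12a (1.28). Without outlying libraries 25 genes passed (8 higher), and 25 with Estop in place of DBD (11 higher).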

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

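The tests of a mislabelled sample, of a mixture of 2 samples, of the vector transcript, of the Htt.HD entry and of genes raised by DBD were chosen after the results were seen. Those of the transcript length trend, with an index chosen after the data were seen, and of CAG repeats were fixed before their own values were seen but after the patterns, and the splits were planned.

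In 60 groups tested, 10 values of single libraries lay far from the others of their group by Dixon's ratio, and chance alone gives such a value in about 1 in 20 groups. Among Htt levels, the library labelled zQ175 nZFP R5 of 6M_8M had 165 CPM (others 75.6 to 118) and the library labelled zQ175 DBD R3 of 2M_6M had 41.8 CPM (83.8 to 109). In 6M_10M the libraries labelled WT DBD R2 and zQ175 nZFP R2 had 44.6 CPM (113 to 148) and 23.4 CPM (72.8 to 92.6), and in 6M_12M the library labelled zQ175 nZFP R1 had 65.7 CPM (78.7 to 88.1). Among signature scores, the libraries labelled zQ175 DBD R1 and zQ175 nZFP R5 of 6M_8M stood at -0.432 (others -0.642 to -0.548) and -1.47 (-0.787 to -0.625). In 6M_10M the libraries labelled zQ175 DBD R4, WT DBD R2 and zQ175 nZFP R2 stood at -1.26 (-1.18 to -1.13), -1.89 (-2.15 to -2.07) and -1.15 (-1.37 to -1.29). The libraries labelled zQ175 DBD R3 of 2M_6M and WT DBD R2 and zQ175 nZFP R2 of 6M_10M also stood apart on the first residual component (robust z 13.9, 7.46 and 8.15).

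Differences between groups were tested directly. The scaled signature score of zQ175 nZFP libraries differed by -0.389 between 2M_6M and 6M_10M (exact permutation p = 0.000333) and by -0.304 between 2M_8M and 6M_12M (exact permutation p = 0.000155). Interactions of virus with genotype passed for 512, 314 and 8 genes in 2M_6M, 2M_8M and 6M_10M. Between paradigms the effect of nZFP in zQ175 mice differed for 2059 genes (2M_6M and 6M_10M; 11 without outlying libraries and 12 with Estop in place of DBD), 14 (2M_8M and 6M_12M), 1 (6M_8M and 6M_12M) and 9 (2M_8M and 6M_8M), and the genotype effect for 40 (2M_6M and 6M_12M). Outside the main measurement, the repressor entry held reads in libraries of viruses without it, at medians of 8.26 CPM under DBD and 10.6 CPM under Estop, against means of 380 to 700 CPM in the zQ175 nZFP groups.

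In 6M_8M, vector transcripts of the 3 libraries labelled WT DBD R7 and R8 and zQ175 nZFP R5 went against their labels. WT DBD R8, fitted as female, held 23.3 CPM of the Y-linked Eif2s3y (other females at most 0.815) and 6.17 Htt.HD counts. A mixture of 2 samples is argued against, since the 3 scores lay at a position of at least 0.964 between the labelled group (0) and the other group (1), where a mixture would lie between. A mislabelled sample remains a candidate explanation for each, as all 3 signature scores (-0.698, -0.698 and -1.47) lay outside the labelled group and near the other one. Which libraries they are instead stays open, and no biological explanation was tested.

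Reversal of the genotype signature was smaller after injection at 6 months than at 2 months. At 6 months of treatment, less vector transcript after late injection is argued against, with a late to early ratio of the repressor entry of 1.71 (95% interval 1.29 to 2.33). At 4 months of treatment it stays open, with a ratio of 0.787 (95% interval 0.642 to 0.990). A transcript length trend is argued against as the whole cause, since at least 95.9% of the difference was left after adjustment to one length index (exact permutation p = 0.000333 for 2M_6M and 6M_10M). Weaker lowering of the Htt.HD entry stays open, with a late minus early difference of -20.5 percentage points (95% interval -85.3 to 8.29) from an entry of few reads. Protein levels, the age at injection and the cohort stay open as untested. The age at collection stays open too: it was equal in 2M_8M and 6M_8M, whose scaled scores differed by -0.376 without the libraries that contradict their labels (exact permutation test, Benjamini-Hochberg 0.000466; 0.235 with them), but months of treatment differed there.

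In WT mice, 31 genes were lower under nZFP than under DBD in at least 3 paradigms, of which 21 were lower in zQ175 mice in at least 3 paradigms too. That DBD raised them is argued against for the set, since 74.2% of them (23) were also lower against Estop in at least 3 paradigms, but Klf14, Mkrn3 and Nup62cl were higher under DBD than under Estop. A run of at least 6 CAG or CTG units lay in an annotated transcript of 8 of the 31 genes (25.8%), among them Nap1l3 (8 units), Tceal6 (6) and Dach1 (6), against a mean of 0.512 genes in 10000 random sets matched for transcript length (one-sided permutation p = 1e-04, the smallest these can give) and 279 of 15257 tested genes (1.83%). Repression through CAG repeats of the WT genome is therefore a candidate explanation for these 8 genes. It stays open for the others, as promoters and introns were not searched and secondary effects were not tested.

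Other splits into groups of the same sizes were tried, 40 per comparison with the real one, in fits of the compared groups alone. Pairwise splits parted as many mouse pairs. For the genotype effect under DBD only the real split was as large (1 of 40 in each paradigm), with 1709, 2431, 1367, 3523 and 1680 genes against at most 100, 1, 3, 1709 and 1 in another split. The split with 1709 genes in 6M_10M points to a structure of the samples apart from the groups. For nZFP in zQ175 mice it can be excluded in each paradigm (800, 670, 5, 63 and 242 genes, at most 0 in another), as for nZFP in WT mice (33, 237, 6, 24 and 15, at most 0, 1, 0, 0 and 0) and the genotype effect under nZFP (555, 279, 1340, 1590 and 3045, at most 0, 1, 5, 1 and 0).

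Between DBD and Estop in zQ175 mice, chance cannot be excluded in 2M_6M (2 genes, 2 in another split, 2 of 40 as large) and can be elsewhere (16, 6, 29 and 33, at most 0, 1, 1 and 0). In WT mice it cannot be excluded in 2M_6M either (11 genes, 28 in another split, 2 of 40) and can be elsewhere (13, 24, 41 and 11, at most 0 in another). For the interaction and between paradigms, splits ignored the mouse, so they cannot exclude chance. The interaction gave 226 in 2M_8M (at most 0 in another), 295 in 2M_6M (691, 2 of 40) and 1 in 6M_10M (1, 2 of 40). Effects of nZFP gave 27 for 2M_6M and 6M_10M, 25 for 2M_8M and 6M_12M and 4 for 2M_8M and 6M_8M (at most 0 each). The genotype effect gave 9 for 2M_6M and 6M_12M (889, 2 of 40). With a real count of 0 every split is as large (40 of 40). This held for the interaction in 6M_8M (0 and 1) and 6M_12M (0 and 7352) and for nZFP between 6M_8M and 6M_12M (0 and 28). Splits that called many more genes than the real one, 28, 691, 7352, 28 and 889, point to a structure of the samples.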

How the results depend on the processing

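Estop in place of DBD, DESeq2 and its size factors (RLE), no count filter, no sex covariate, both blocks, the estimated correlation and other choices of the signature were planned, while the length index covariate, the mouse block on the scores and the fits without contradicting or outlying libraries were chosen after seeing the data. Of 5193 values of named genes under these alternatives, 5019 kept their direction and their side of the threshold. Over 330 settings of 40 counts, those that moved by over 1.5 times are given below, and the cause was not tested for any value here. Score results, after Benjamini-Hochberg adjustment, kept both with a signature common to all paradigms, one at an adjusted p of 0.01, one chosen from DBD libraries and scored with Estop, a prior count of 0.5, and the mouse as a block on the scores. Depth limits the Htt.HD entry (at most 11.6 counts) and genes near 1 CPM (28.0 to 61.4 counts).

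Blocking by mouse moved 20 of 25 counts. Counts for nZFP in zQ175 mice became 732 in 2M_6M, 5 in 6M_8M, 101 in 6M_10M and 360 in 6M_12M. For nZFP in WT mice they were 221 in 2M_8M, 3 in 6M_8M, 44 in 6M_10M and 63 in 6M_12M. Between DBD and Estop they were 69 in 2M_6M, 5 in 6M_8M, 10 in 6M_10M and 173 in 6M_12M in zQ175 mice, and 78 in 2M_8M, 15 in 6M_8M, 50 in 6M_10M and 59 in 6M_12M in WT mice. For the interaction they were 107 in 2M_6M, 643 in 2M_8M, 1 in 6M_10M and 15 in 6M_12M. Htt changed sign under this block for nZFP in zQ175 mice of 6M_8M (0.0055) and in WT mice of 6M_12M (-0.081) and for DBD in zQ175 mice of 6M_10M (0.21), none of them past the threshold, and DBD passed for Htt in zQ175 mice of 6M_12M (-0.37, adjusted p = 0.0261). Apart from the calls named here, in the report and among the lists, the mouse block ended no other call of a named gene.

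With replicate numbers as a block, counts were 3035 for nZFP in zQ175 mice, 4811 for genotype under DBD and 6655 for genotype under nZFP in 6M_12M. For nZFP in WT mice they were 728 in 2M_8M, 125 in 6M_10M and 73 in 6M_12M. Between DBD and Estop this block gave 103 in 2M_6M, 5 in 6M_8M and 79 in 6M_12M in zQ175 mice and 67 in 6M_12M in WT mice, and for the interaction 16 in 6M_10M and 83 in 6M_12M. Htt changed sign for nZFP in zQ175 mice of 6M_12M (0.016) and for DBD in zQ175 mice of 2M_8M (0.025), neither past the threshold.

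With Estop in place of DBD, counts were 2354 for genotype in 6M_8M, 1157 for nZFP in zQ175 mice of 2M_6M, and 92 in 2M_6M, 153 in 2M_8M, 7 in 6M_8M and 56 in 6M_12M for nZFP in WT mice. The interaction gave 204 in 2M_6M, 2 in 6M_10M and 6 in 6M_12M. Differences between paradigms gave 12 for 2M_6M and 6M_10M, 2 for 6M_8M and 6M_12M, and 25 for the genotype effect. In WT mice Htt changed sign (-0.10 in 2M_6M, -0.17 in 6M_8M, -0.12 in 6M_10M and -0.17 in 6M_12M, none past the threshold), as did Klf14 (1.80, 1.64, 0.33, 1.46 and 1.80, past it in all but 6M_8M) and Mkrn3 (0.23, 0.26, 0.41, 0.36 and 0.45, none past it). Ttr changed sign for genotype in 6M_8M (2.45, adjusted p = 0.403).

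DESeq2 gave 46 for nZFP in zQ175 mice of 6M_8M, and 940 in 2M_8M, 295 in 6M_8M and 127 in 6M_10M for nZFP in WT mice. Between DBD and Estop it gave 1127 in 2M_6M, 45 in 2M_8M and 24 in 6M_8M in zQ175 mice and 63 in 2M_8M, 65 in 6M_8M and 47 in 6M_12M in WT mice, and for the interaction 37 in 6M_10M and 11 in 6M_12M. Between paradigms it gave 67 for 2M_8M and 6M_12M (39 with RLE size factors in edgeR), 24 for 2M_8M and 6M_8M, 10 for 6M_8M and 6M_12M, and 71 for the genotype effect. Without a count filter, more genes were tested and 93 passed in 2M_6M and 18 in 2M_8M between DBD and Estop in zQ175 mice, and 206 for nZFP in WT mice of 2M_8M. Without the sex covariate, 465 passed between DBD and Estop in zQ175 mice of 2M_6M and 1 for the interaction in 6M_10M.

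The length index covariate moved 29 of 40 counts. The first residual component (22.7 to 42.1% of variance) followed it in all but 6M_8M (r = 0.95, -0.98, -0.07, 0.99 and 0.98). The order here is 2M_6M, 2M_8M, 6M_10M and 6M_12M. Genotype under nZFP gave 697, 2702, 5258 and 4080 and nZFP in WT mice 86, 293, 400 and 146. Between DBD and Estop counts were 78, 72, 109 and 117 in zQ175 and 35, 131, 433 and 122 in WT mice. The interaction gave 936, 1184, 55 and 71. Genotype under DBD gave 5399, 6155 and 5501 from 2M_8M on, and nZFP in zQ175 mice 2209, 409 and 630 there and 31 in 6M_8M. Between paradigms they were 662 for 2M_6M and 6M_10M and 19 for 2M_8M and 6M_8M. Htt changed sign for the interaction in 2M_8M (-0.013, adjusted p = 0.954), and passed for genotype under nZFP in 2M_8M (-0.62) and 6M_8M (-0.58) and for DBD against Estop in 6M_12M in zQ175 mice (-0.31) and in 6M_10M in WT mice (-0.23).

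Without outlying libraries, counts were 2165 for nZFP in zQ175 mice of 2M_6M, 74 in 2M_6M and 157 in 6M_10M for nZFP in WT mice, and 623 for genotype under nZFP in 2M_6M. Between DBD and Estop they were 79 in 2M_6M and 78 in 6M_10M in zQ175 mice and 46 in 2M_6M and 249 in 6M_10M in WT mice. Between paradigms they were 11 for 2M_6M and 6M_10M and 25 for the genotype effect. Without libraries that contradict their labels, counts in 6M_8M were 2708 for genotype under DBD, 29 for nZFP in zQ175 mice and 15 for DBD against Estop in zQ175 mice, and between paradigms 71 for 2M_8M and 6M_12M and 60 for 2M_8M and 6M_8M. The scaled signature score of 6M_8M minus 6M_12M changed sign to 0.0715 (exact permutation test, Benjamini-Hochberg 0.00311), though the bootstrap intervals of reversal overlapped. The score of 2M_8M minus 6M_8M went to -0.376 and passed (exact permutation test, Benjamini-Hochberg 0.000466). Shox2 for nZFP in WT mice of 6M_8M changed sign to 0.41 (adjusted p = 0.647).

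With an estimated correlation between genes, list tests past the threshold over the 5 paradigms were 26 for genotype under DBD, 18 for nZFP in zQ175 mice, 0 for nZFP in WT mice, 15 for genotype under nZFP, 4 and 0 for DBD against Estop in zQ175 and WT mice, and 10 for the interaction, against 48, 56, 19, 48, 30, 31 and 39 by camera with its preset correlation. Under the mouse block list tests past the threshold numbered 59 and 23 for nZFP in zQ175 and WT mice, 36 and 33 for DBD against Estop, and 36 for the interaction. There, oxidative phosphorylation calls for nZFP in zQ175 mice were lost in 2M_6M, 2M_8M and 6M_12M (adjusted p = 0.0542, 0.247 and 0.520) and gained in 6M_8M (1.00e-06, lost with an estimated correlation at 0.604), the direct pathway call was lost in 6M_10M (0.312) and gained in 6M_8M (0.0273), and immediate early genes passed in 2M_6M (3.97e-06) and 2M_8M (3.80e-05) and not in 6M_10M (0.354). With an estimated correlation and the block, immediate early genes held in 2M_6M (0.00815) but not in 2M_8M (0.168), the direct pathway call of 6M_8M was lost (0.165), and interneuron genes held in 2M_8M (0.0433) and astrocyte genes in 6M_10M (0.0411). The block also ended interaction calls of protocadherins (0.470) and cortical genes (0.0545) in 2M_8M, where immediate early genes gained a call (1.08e-06, lost with an estimated correlation at 0.118), and the identity call between DBD and Estop in WT mice of 6M_8M (0.0610). For the interaction with an estimated correlation, the block ended the calls of potassium channels in 2M_6M (0.0977) and homeobox factors in 2M_8M (0.0508), while immediate early genes, homeobox factors and cortical genes held in 2M_6M (0.00204, 0.0313 and 0.0352).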

Other observations

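All genes named in this part are members of lists chosen beforehand and were picked after their values were seen.

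Astrocyte genes were lower with genotype, and single glial and immune genes moved either way. Of 13 astrocyte genes, 6, 6, 3, 5 and 5 were lower in zQ175 mice under DBD (9, 7, 5, 8 and 9 adjusted over the list alone), among them the glutamine synthetase Glul in all 5 paradigms (-0.33, -0.37, -0.24, -0.31 and -0.41). Camera called the list in every paradigm, and 2M_8M and 6M_12M held with an estimated correlation (adjusted p = 0.464, 0.0171, 0.377, 0.305 and 0.0192). S100b went the other way and rose by 0.87, 0.54 and 0.51 in 2M_6M, 2M_8M and 6M_12M (0.37 in 2M_6M and 0.54 in 6M_10M, both passing, without outlying libraries). In 6M_12M the reactive astrocyte genes Gfap (0.85, SE 0.22) and Serpina3n (0.91, SE 0.18) and the microglial gene Cst7 (1.52, SE 0.39) rose, and Serpina3n had risen by 0.42 in 2M_6M (0.41, adjusted p = 0.0551 without the library labelled WT DBD R6). Fbln5, of the reactive astrocyte list, fell by 0.75, 0.77, 0.58, 0.82 and 0.80. The chaperone gene Hspa1a rose by 0.47, 0.31 and 0.60 in 2M_8M, 6M_10M and 6M_12M. The p53 targets Cdkn1a (-0.63 to -0.80) and Plk2 (-0.31 to -0.53), the myelin gene Mal (-0.33 to -0.45), the sterol gene Acat2 (-0.23 to -0.41) and Cd4 (-0.70 to -0.85) were lower in all 5 paradigms.

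Genes of cortical excitatory neurons rose in zQ175 striatum. The count table held 10 entries of this list, and genes with few reads in WT mice could pass the count filter only through zQ175 groups. Higher were 3 of 6, 3 of 6, 2 of 9, 5 of 8 and 5 of 8 tested members (3, 3, 4, 5 and 5 adjusted over the list alone), with Neurod2 at 3.31, 3.69 and 5.39 in 2M_8M, 6M_10M and 6M_12M, and at 2.42 in 6M_8M (adjusted p = 0.046) without the libraries that contradict their labels. Camera called the list in the last 4 paradigms (adjusted p = 0.0116, 0.445, 0.00227 and 0.000348 with an estimated correlation). Under nZFP in zQ175 mice 2, 3, 0, 1 and 2 members were lower (2, 3, 0, 2 and 3 adjusted over the list alone), with calls in 2M_8M, 6M_10M and 6M_12M (0.0122, 0.00967 and 0.00545 with an estimated correlation; 0.0184, 0.0776 and 0.0103 with the mouse as a block too, so that 6M_10M was lost). Interneuron genes were lower with genotype for 2, 4, 0, 2 and 3 of 14 members (2, 5, 0, 2 and 3 adjusted over the list alone), called by camera in the last 4 paradigms and in none with an estimated correlation (0.196, 0.0698, 0.0646 and 0.162). They were higher under nZFP for 5, 2, 0, 1 and 0 members (6, 3, 0, 1 and 3 adjusted over the list alone), called in 2M_8M, 6M_10M and 6M_12M (0.202, 0.00981 and 0.0657 with an estimated correlation). Egr2, an immediate early gene, rose under nZFP in zQ175 mice by 1.69 and 1.43 in 2M_6M and 2M_8M (1.66, adjusted p = 0.0524 in 2M_6M without the library labelled zQ175 DBD R3).

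The remaining lists gave few calls for genotype under DBD. Microglial genes were lower for 3, 3, 0, 2 and 1 of 16 members (1, 3, 0, 2 and 1 adjusted over the list alone), with camera calls in 2M_8M, 6M_8M and 6M_10M lost with an estimated correlation (adjusted p = 0.514, 0.626 and 0.732). Endothelial genes were lower for 0, 3, 0, 0 and 2 of 10 (0, 4, 0, 0 and 2 adjusted over the list alone), called in 2M_8M (0.0199 with an estimated correlation). Reactive astrocyte genes were called in 6M_8M (0.628 with an estimated correlation), with 1, 0, 0, 0 and 3 higher and 1 lower in each paradigm. Lists without a call were oligodendrocytes (4, 4, 2, 6 and 4 of 14 lower and 2, 1, 0, 2 and 2 higher), their precursors (1, 0, 0, 0 and 0 of 9 lower and 0, 0, 0, 1 and 1 higher), mural cells and fibroblasts (0 of 10 in edgeR, camera adjusted p from 0.132 to 0.611), disease-associated microglia (1, 0, 0, 0 and 4 of 14 higher and 2, 2, 0, 1 and 3 lower) and type I interferon genes (0, 1, 0, 0 and 2 higher and 1, 1, 0, 1 and 0 lower). MHC class I (1, 1, 0, 0 and 2 of 13 higher and 1 lower in 6M_10M) and class II (2 and 1 lower in 6M_10M and 6M_12M), T and NK cells (2, 1, 1, 0 and 1 higher and 1 lower in each), B cells (1 lower in 2M_6M and in 2M_8M) and choroid plexus (1, 1, 0, 1 and 1 higher, 1 lower in 6M_8M) had none either. The same held for pallidal, septal and cholinergic forebrain (1, 1, 0, 1 and 1 of 8 higher and 2, 2, 0, 2 and 3 lower), cholesterol synthesis (3, 1, 1, 2 and 2 of 23 higher and 2, 4, 2, 6 and 2 lower), heat shock (1, 2, 0, 2 and 4 of 15 higher and 0, 1, 0, 0 and 1 lower), p53 (1, 2, 0, 1 and 2 of 16 higher and 5, 4, 2, 4 and 3 lower) and polyglutamine disease genes (1, 2, 0, 1 and 1 of 8 higher and 1, 0, 1, 1 and 1 lower).

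In 2M_6M, oxidative phosphorylation genes were higher with genotype for 35 of 77 members (45 adjusted over the list alone, adjusted p = 0.828 with an estimated correlation) and ependymal genes for 6 of 7 (7 adjusted over the list alone, 0.660), and 2 and 1 were higher without the library labelled zQ175 DBD R3. Ccdc153, an ependymal gene, stood at 3.69 (SE 1.00) with that library and at 1.21 without it (adjusted p = 0.356). The choroid plexus gene Ttr stood at -6.49 (SE 2.00) in 6M_8M and at 2.45 with Estop in place of DBD (adjusted p = 0.403).

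Under nZFP in zQ175 mice, immune lists were called by camera in some paradigms and none held with an estimated correlation. Microglial genes were higher for 4 and 2 of 16 members in 2M_6M and 2M_8M (5 and 9 adjusted over the list alone, adjusted p = 0.622 and 0.238 with an estimated correlation), and interferon genes for 6 of 17 in 2M_6M (0.622). MHC class I and class II genes were called in 2M_8M (0.238 and 0.202) and 6M_10M (0.416 and 0.448), B cells in 2M_6M and 2M_8M (0.551 and 0.202) and polyglutamine disease genes, with 2 of 8 lower, in 2M_8M (0.337).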
